A study of Mus musculus with 20 samples.

How the data were processed

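RNA of the forebrain of 20 mouse embryos was hybridised to Affymetrix Mouse Gene ST 1.0 arrays, 1 embryo per array. Per the labels' protocols, Ts1Cje males were mated to C57Bl/6J females, breeding pairs ate purified powdered chow with or without apigenin, and only RNA with an integrity number above 9 was used. The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, makes the arrays' distributions alike and summarises the probes of a set. Its version, the chip definition and the genome build are not given in the sources used here. Because of it, differences of an array's overall level were removed before deposit, and low values are compressed toward the background, so fold changes of dim genes are understated.

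The table holds 21225 probe sets. A gene table paired 20239 of them with 1 gene symbol each by Entrez gene number, 0 with several, and 986 were not listed there and are unnamed here. No symbol had more than 1 probe set, so probe sets were used as genes, and 0 symbols needed an update. Neighbouring genes were taken from a table of the GRCm38.p6 assembly, used for gene order only, with no coordinates. Columns of samples outside the series numbered 0. Groups came from the genotype and treatment fields of the labels, because the titles of all 20 samples carry the strain name Ts1Cje. The level of the trisomic segment was checked against these labels in every array.

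Differential expression was tested in R 4.3.3 with limma 3.58.1. A model with 1 mean for each of the 4 groups was fitted with lmFit and eBayes over all 20 arrays, which share 1 estimate of spread per gene. The contrasts were genotype on each chow, treatment in each genotype, the interaction, and both main effects averaged over the other factor. Tests were two-sided with Benjamini-Hochberg adjustment over 20239 genes and a threshold of 0.05. The study's own methods name unpaired t-tests and an analysis of variance with a p threshold of 0.001 and a false discovery rate of 10%, and these were run as alternatives. A count of calls adjusted over the list alone used the members of that list only.

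The 35 gene lists tested were the trisomic segment, chromosome 16 genes proximal to it, distal chromosome 12, interferon response, NF-kB and cytokine signalling, NRF2 and antioxidant defence, aryl hydrocarbon receptor targets, oxidative phosphorylation, glycolysis and hypoxia, G1/S and DNA replication, G2/M and mitosis, p53 targets, endoplasmic reticulum stress, heat shock, immediate early genes, cholesterol synthesis, neurotrophin signalling, hedgehog and Wnt signalling, synapse and ribosomal proteins, and markers of radial glia, intermediate progenitors, deep-layer, upper-layer, Cajal-Retzius, interneuron and striatal neurons, diencephalon, hippocampus and hem, choroid plexus, oligodendrocyte precursors, microglia, endothelium, erythroid cells and meninges. Y-linked genes served to check the sex balance. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with the correlation estimated per list and fry were alternatives. The level of the segment was the mean log2 value of its members per embryo, compared by exact permutation.

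The genes named were chosen by a rule: in each comparison the 10 genes with the smallest p that rose and the 10 that fell among those past the threshold, the 5 with the smallest p where fewer than 5 passed, and up to 4 members with the smallest p of each list described. The design, the groups, the lists, this rule and the alternatives were fixed before the data were examined, except the alternatives and genes said to have been chosen afterwards. Correlations of fold changes were set beside 1000 simulations of groups with no effect, and shared lists of calls beside the overlap of independent lists.

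Each test was tested on simulated data with 200 changed genes. On plain chow the genotype test called 6% of genes changed 1.1-fold, 66% at 1.25-fold, 98% at 1.5-fold and 100% at 2-fold, with 5 false calls. In WT the treatment test called 6%, 76%, 96% and 98%, with 7 false calls, and in Ts1Cje 14%, 68%, 94% and 100%, with 6. The simulated noise was independent between genes and between embryos. In the data 2492 genes in WT and 3291 in Ts1Cje passed by treatment, and so many calls loosen the adjusted threshold. The simulated shares and false calls therefore do not describe the treatment tests on these data. For genotype on plain chow the data gave 63 calls against 140 in the simulation. The threshold was thus stricter in the data, and the simulated shares are too high there. Alternatives were other thresholds and tests, filters on the dimmest 20% and 40% of genes, renewed normalization, array weights, a trended robust prior, blocks of embryo number runs, the Y-linked level as a covariate and leaving out each array. No probe set was left out of the main tests for being dim. The human cells named in the design text were not analysed here.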

Results

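Gene expression was measured in the forebrain of 20 mouse embryos on the Affymetrix Mouse Gene ST 1.0 array, with 1 embryo per array. Ts1Cje mice carry an extra copy of the distal part of chromosome 16, which holds counterparts of many genes of human chromosome 21, and the extra part is translocated to the end of chromosome 12. Apigenin is a plant flavone that was mixed into the powdered chow of the breeding pairs at 2 g per kg from the time of mating. The labels put the dose at 333 to 400 mg per kg body weight per day. The series title names it as a possible treatment before birth for trisomy 21. The 4 groups of 5 embryos were wild-type (WT) on plain chow, Ts1Cje on plain chow, WT on apigenin and Ts1Cje on apigenin. The sample labels give embryonic day 15, and the protocol a time later on that day. The design text gives 3 males and 2 females per group, and in each group 3 arrays had high Y-linked signal (9.00 to 9.49 on the log2 scale) and 2 had low signal (4.53 to 4.89). Xist, the RNA of the inactive X chromosome, lay at 12.2 to 12.4 in the arrays with low Y-linked signal and at 5.02 to 5.89 in the others.

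The arrays were alike in scale, with group medians of 7.84 to 7.85 on the log2 scale, and every pair of arrays correlated at 0.991 to 0.997 across genes. No 2 arrays were identical. The first principal component, 21.3% of the variance, put the plain chow arrays at -15.7 to -2.47 and the apigenin arrays at 4.10 to 11.9. WT plain chow replicate 1 lay farthest out on the first and second components, at -15.7 and 16.4. The number of arrays, 5 per group, limits the precision of every value. The embryos' litters are not given in the labels, so p-values measure the spread between embryos, some of which may have shared a dam. The embryo numbers in the titles ran from 87 upward on plain chow and from 1 to 59 on apigenin, so treatment and embryo number cannot be told apart.

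The first question was which genes the segmental trisomy changed on plain chow. Most of the change lay in the trisomic segment itself: of 68 genes listed beforehand for the segment, all measured, 42 were higher in Ts1Cje, 0 were lower and 26 did not pass. Adjusted over the list alone, 51 were higher and 1 was lower. The median fold over the list was 1.26, and the list passed camera with a preset correlation (adjusted p = 2.2e-115) and with an estimated one (1.9e-13). Examples were Son, an RNA splicing factor, at 0.50 ± 0.04 (log2 fold change ± SE, n = 5 per group), Dyrk1a, a protein kinase, at 0.32 ± 0.03, Synj1, a phosphatase of synaptic vesicle recycling, at 0.40 ± 0.04, and the interferon receptor subunits Ifnar1 at 0.38 ± 0.04 and Ifngr2 at 0.41 ± 0.04. Vps26c (0.48), Dop1b (0.45), Cryzl1 (0.44) and Paxbp1 (0.52) also rose. Of the 25 genes listed from the part of chromosome 16 just before the segment, 0 changed over all genes or adjusted over the list alone, with a median of 0.01.

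The segment's mean level separated the genotypes completely on both chows. On plain chow it was 8.42 ± 0.013 in WT and 8.70 ± 0.0093 in Ts1Cje (log2, SD, n = 5 each), a difference of 0.28 (SE 0.0071), with a two-sided exact permutation p of 0.0079, the smallest that the assignments of 5 against 5 allow. On apigenin it was 8.41 ± 0.0079 and 8.69 ± 0.012, a difference of 0.28 (SE 0.0065) with the same exact p of 0.0079. The 2 differences differed by 0.0046 (95% interval -0.016 to 0.025), which was not past the spread between embryos (two-sided exact permutation p = 0.645, 63504 assignments). Within runs of neighbouring embryo numbers the difference was 0.27 and 0.29 on plain chow and 0.28 and 0.28 on apigenin. Averaged over chows, 41 of the 43 members above the median level of all genes rose, with a median fold of 1.32, against 6 of the 25 dimmer members.

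**Figure D1:**
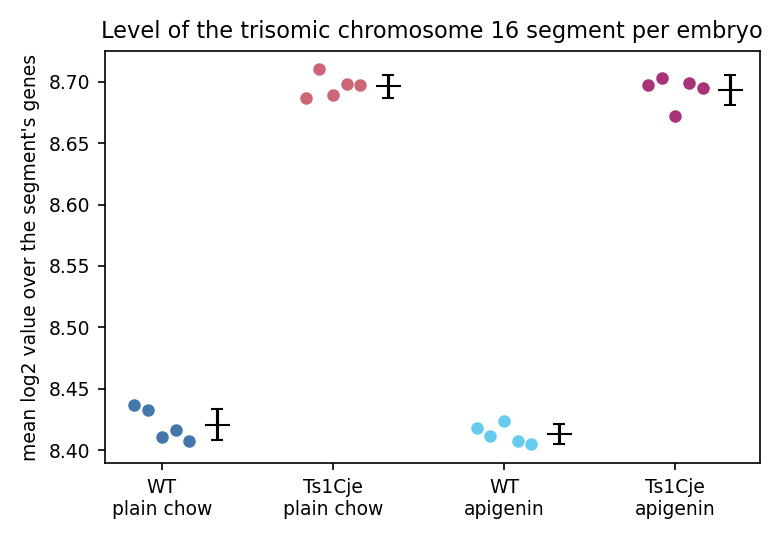
Mean log2 value of the genes of the trisomic chromosome 16 segment for each embryo, by genotype and chow, with each dot an embryo and the bar the group mean ± SD (n = 5). The 10 Ts1Cje embryos lay above the 10 WT embryos, at group means of 8.70 and 8.69 against 8.42 and 8.41.

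Over the whole array 63 genes differed between Ts1Cje and WT on plain chow, 53 higher and 10 lower, and 21 of them lay outside the listed segment, 11 higher and 10 lower (limma, adjusted p under 0.05, 20239 genes). The largest change of all was in Dnah11, an axonemal dynein gene of chromosome 12, which was 11.6-fold higher in Ts1Cje (3.54 ± 0.06, adjusted p = 2.5e-19), from 7.05 ± 0.18 in WT to 10.59 ± 0.05 (log2, SD, n = 5). Its neighbours went the other way: Itgb8, an integrin subunit, at -0.71 ± 0.05, Tmem196 at -0.50 ± 0.07, and the transcription factors Sp4 at -0.41 ± 0.05 and Sp8, used in interneuron progenitors, at -0.30 ± 0.05. Of the 9 listed distal chromosome 12 genes 1 rose, 4 fell and 4 did not pass, and the counts were 1 and 4 adjusted over the list alone. The list's median (-0.03) and mean (0.19) differed in sign, and camera gave an adjusted p of 0.076. In the GRCm38.p6 gene order the lower genes lie between Dnah11 and the end of the chromosome, where Abcb5 and Macc1, between them, were dim at 5.16 and 4.98. Bright genes before Dnah11, such as Cdca7l (0.08) and Rapgef5 (0.04), did not pass. These 4 dim or unmoved neighbours were named after their values were seen.

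Elsewhere in the genome, Gngt2, a G protein subunit of cone photoreceptors, lay at -0.34 ± 0.06, Rfx5, a regulator of MHC class II genes, at -0.30 ± 0.06, Cpne6 at -0.33 ± 0.06, Dnajc5b at -0.32 ± 0.06, Smim20 at -0.27 ± 0.05 and Ddit4, a stress-induced inhibitor of mTORC1, at -0.30 ± 0.06. Sod1, next to the segment and chosen after its values were seen, rose by 0.35. The count outside the segment was 7 with the methods' t-test after Benjamini-Hochberg adjustment and 10 with only the groups compared in the model. It was 38 without WT plain chow replicate 2, and 13 without WT plain chow replicate 5 or without Ts1Cje plain chow replicate 3.

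**Figure D2:**
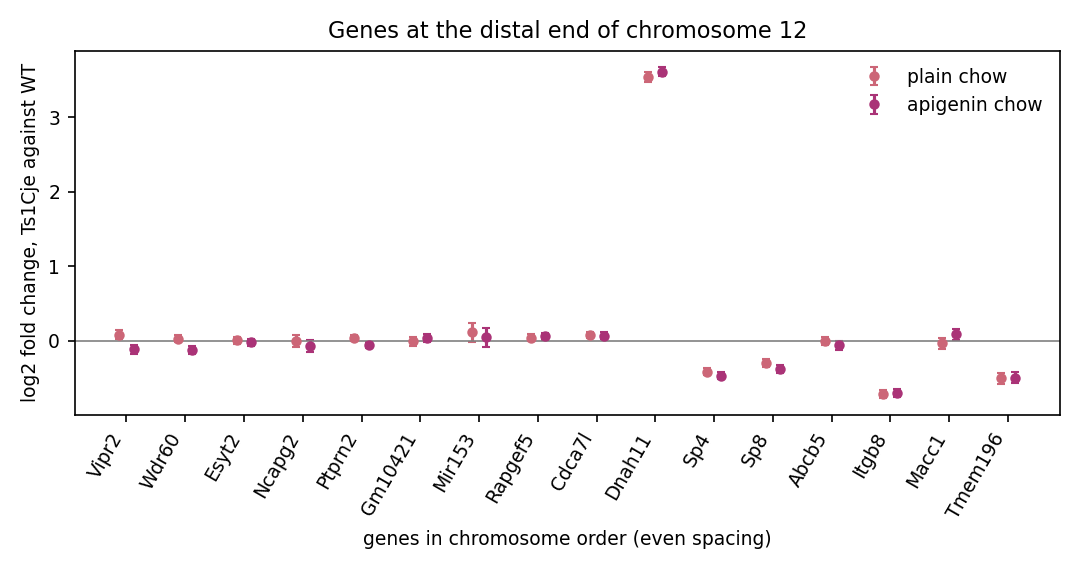
Log2 fold change of Ts1Cje against WT (y axis) for the measured genes from Vipr2 to the end of chromosome 12, in GRCm38.p6 gene order with even spacing (x axis), as points ± SE on plain and apigenin chow (n = 5 per group). Dnah11 lay at 3.54 and 3.61, and Sp4, Sp8, Itgb8 and Tmem196 lay between -0.71 and -0.30.

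Of the other gene lists, 4 shifted on plain chow by camera although 0 of their members passed singly, over all genes or adjusted over the list alone. None of the 4 held when the correlation between genes was estimated. The median was 0.04 for 30 endothelial and pericyte genes (adjusted p = 7.0e-05, lost at adjusted p = 0.395 with an estimated correlation). It was 0.06 for 44 interferon response genes (adjusted p = 8.4e-05, lost at 0.395 with an estimated correlation). It was 0.05 for 34 genes of meninges and fibroblasts (adjusted p = 0.0034, lost at 0.877 with an estimated correlation). For 39 genes of NF-kB and cytokine signalling it was -0.06 (adjusted p = 0.0052, lost at 0.513 with an estimated correlation). Among the members with the smallest p, the blood-brain barrier transporter Slco1c1 had 0.18 ± 0.06, the endothelial cadherin Cdh5 0.15 ± 0.05, Xaf1 0.17 ± 0.06, Postn 0.20 ± 0.06 and the TNF receptor Tnfrsf1a -0.16 ± 0.05, with none past the threshold.

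On apigenin chow 63 genes again differed between Ts1Cje and WT, 53 higher and 10 lower, with 21 outside the segment, 11 higher and 10 lower. These 21 included 5 genes of chromosome 12, all at its distal end, and 2 genes that flank the listed segment on chromosome 16. The flanking genes were Sod1 (0.22) and A630089N07Rik (0.41), both chosen after their values were seen. A630089N07Rik lies beyond the last listed gene, on the distal side, so the extra copy may cover it. Counts outside the segment refer to the list, so such genes enter them. In the segment 42 of 68 genes rose, 0 fell and 26 did not pass (49 and 0 adjusted over the list alone), and 40 genes of the segment rose on both chows. Dnah11 was 12.2-fold higher (3.61 ± 0.06), Son lay at 0.51 ± 0.04, Ifnar1 at 0.45 ± 0.04, Il10rb at 0.39 ± 0.04 and Cbr1, a carbonyl reductase, at 0.47 ± 0.05. Itgb8 (-0.69), Sp4 (-0.46), Tmem196 (-0.49), Sp8 (-0.37) and Rfx5 (-0.39) were lower once more. Scgn, a calcium-binding protein, was at -0.28 ± 0.05, Gng4 at -0.31 ± 0.06, Impg2 at -0.33 ± 0.07, Catsperg1 at -0.51 ± 0.09 and the dim gene Gm7168 at -0.50 ± 0.10. Between the lists of calls on the 2 chows 43 genes were higher in both, 5 lower in both and 0 opposite, where independent lists would share 0.139 and 0.0049 genes. The chows share no arrays, and the log2 fold changes correlated at r = 0.32 across genes, within the range of -0.59 to 0.50 of simulated groups with no effect. Without the dimmest 40% of genes r was 0.608, also within its own simulated range of -0.634 to 0.609. Genes are not independent replicates.

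No list besides the segment shifted on apigenin by camera, the next being the ganglionic eminence and interneuron list, in which 0 of 26 genes rose and 1 fell (0 and 1 adjusted over the list alone, median -0.03, adjusted p = 0.0683). This rests on single arrays: the number of lists past camera, the segment included, was 1 with all arrays and was higher in 8 of the 20 fits that left 1 array out, with as many as 6 without WT apigenin replicate 4. The count of genes outside the segment was 13 without WT apigenin replicate 1 or without Ts1Cje apigenin replicate 3, and 56 by the methods' t-test at their unadjusted p threshold. Averaged over both chows 126 genes differed by genotype, 99 higher and 27 lower, and 79 lay outside the segment. The count was 205 at the study's threshold and 200 without the dimmest 40% of genes, and the count outside the segment was 131 without WT plain chow replicate 2. The averaged calls added Rec8, a meiotic cohesin, at -0.22 ± 0.04 and Hdac10 at -0.16 ± 0.03. On the averaged contrast, 3 lists passed camera besides the segment: interferon response (adjusted p = 0.0015, median 0.04, 0 of 44 singly, over all genes and adjusted over the list alone), meninges (adjusted p = 0.0377, median 0.02, 0 of 34 singly, with 1 higher adjusted over the list alone) and distal chromosome 12 (adjusted p = 0.0453, median -0.03 and mean 0.19, 1 higher and 4 lower of 9, with 2 and 4 adjusted over the list alone). These were lost, with an adjusted p = 0.689 with an estimated correlation for interferon response and distal chromosome 12, and 0.775 for meninges. The number of lists, 4 with the segment included, ranged from 2 to 6 when single arrays were left out.

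The next question was what apigenin changed. In WT embryos, genes of dividing cells rose and genes of synapses fell. Of 48 measured genes of G2/M and mitosis 44 rose, 0 fell and 4 did not pass (45 and 0 adjusted over the list alone), with a median of 0.35. Ect2, which drives cytokinesis, rose by 0.51 ± 0.06, Cenpa, the centromeric histone, by 0.38 ± 0.05, and the spindle motor Kif11 by 0.39 ± 0.06. Of 43 genes of G1/S and DNA replication 28 rose and 0 fell (33 and 0 adjusted over the list alone, median 0.24), among them the replicative helicase subunits Mcm2 (0.42 ± 0.04) and Mcm3 (0.49 ± 0.06), the ribonucleotide reductase subunit Rrm2 (0.47 ± 0.07) and the cyclin Ccnd2 (0.35 ± 0.05). By camera the adjusted p was 7.85e-33 for G2/M and 8.4e-24 for G1/S. The G2/M list was lost, at adjusted p = 0.0626 with an estimated correlation, and the G1/S list held at 0.0292. WT plain chow replicate 1 was low in the level of both lists and of the intermediate progenitor list. Its G2/M level was 8.51 against 8.68 to 8.72 in the rest of its group, while the WT apigenin embryos lay at 8.90 to 9.05.

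Lists of neural progenitors rose beside them. Of 21 genes of intermediate progenitors, the dividing cells that give rise to cortical neurons, 13 rose and 0 fell in WT (16 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 4.5e-13, held at adjusted p = 0.0329 with an estimated correlation). Gadd45g rose by 0.62 ± 0.05, Nhlh1 by 0.62 ± 0.09, the proneural factor Neurog2 by 0.50 ± 0.08 and the Notch ligand Dll1 by 0.26 ± 0.04. Of 32 genes of radial glia, the stem cells of the forebrain wall, 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.09, adjusted p = 1.3e-05, lost at 0.159 with an estimated correlation). Nes was at 0.58 ± 0.09, Sox2 at 0.33 ± 0.05 and Vim at 0.27 ± 0.04, and the faller was Tnc, an extracellular matrix protein, at -0.42 ± 0.06. Of 28 genes of hedgehog and Wnt signalling 6 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.10, adjusted p = 1.1e-05, held at 0.0329 with an estimated correlation), led by Cdon, a hedgehog co-receptor, at 0.40 ± 0.06. Of 16 genes of the hippocampus and cortical hem 4 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.0318, lost at 0.176 with an estimated correlation), with Wnt8b at 0.44 ± 0.08 and Grik4, a kainate receptor subunit, at -0.25 ± 0.05.

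Other lists fell in WT. Of 45 synapse genes 25 fell, 0 rose and 20 did not pass (29 and 0 adjusted over the list alone, median -0.19, adjusted p = 3.2e-17, and adjusted p = 0.0124 with an estimated correlation). The GABA receptor subunit Gabra5 was at -0.55 ± 0.06, Camk2b at -0.36 ± 0.06, the postsynaptic scaffold Shank1 at -0.42 ± 0.06 and Nrxn2 at -0.31 ± 0.05. Of 18 genes of striatal neurons 6 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.14, adjusted p = 0.0015, and 0.0329 with an estimated correlation), with the enkephalin precursor Penk at -0.59 ± 0.07, Rgs9 at -0.28 ± 0.05, Rxrg at -0.32 ± 0.07 and the dopamine receptor Drd2 at -0.25 ± 0.06. Of 13 genes of oligodendrocyte precursors 4 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.14, adjusted p = 4.3e-04, lost at 0.0744 with an estimated correlation). Among 19 genes of cholesterol synthesis 3 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.08, adjusted p = 0.0351, lost at 0.733 with an estimated correlation). The fallers included Omg (-0.46 ± 0.10) and Gpr17 (-0.26 ± 0.06) in the first and the farnesyl diphosphate synthase Fdps (-0.18 ± 0.04) and squalene synthase Fdft1 (-0.16 ± 0.04) in the second, and Insig1, a sterol sensor partner, rose by 0.18 ± 0.06.

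In all, 2492 genes differed between chows in WT, 1308 higher and 1184 lower on apigenin (limma, adjusted p under 0.05), most by little, with a median size of 0.22 among them. The largest change, and the only one over 2-fold, was in the embryonic beta-type globin Hbb-y, 6.72-fold higher (2.75 ± 0.24), from 6.97 ± 0.22 to 9.72 ± 0.41 (SD, n = 5). Globin genes of one cluster are close copies, and how well the probes part them was not tested. Igf2bp1, an RNA-binding protein of fetal tissue, rose by 0.49 ± 0.05, the neuronal gene repressor Rest by 0.32 ± 0.04, and Gpc2 (0.37), Mdm1 (0.37), Rcc2 (0.36) and Hnrnpm (0.32) rose. The largest falls by p were in Neto1, a glutamate receptor partner, at -0.58 ± 0.06, the GABA receptor subunit Gabrg3 at -0.44 ± 0.04, the adenylyl cyclase Adcy1 at -0.54 ± 0.06, the fatty acid desaturase Scd1 at -0.75 ± 0.08, acetylcholinesterase (Ache) at -0.54 ± 0.06, and Bend6 (-0.52), Pla2g7 (-0.52), Ckmt1 (-0.50), Cpne4 (-0.49) and 1700086L19Rik (-0.46). The count was 1641 with the methods' t-test after Benjamini-Hochberg adjustment, 865 at its unadjusted p threshold, 1574 with only the groups compared in the model, and 1 with the G2/M level as a covariate, which itself differed between the chows. Without any single array it stayed between 1906 and 2508.

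**Figure D3:**
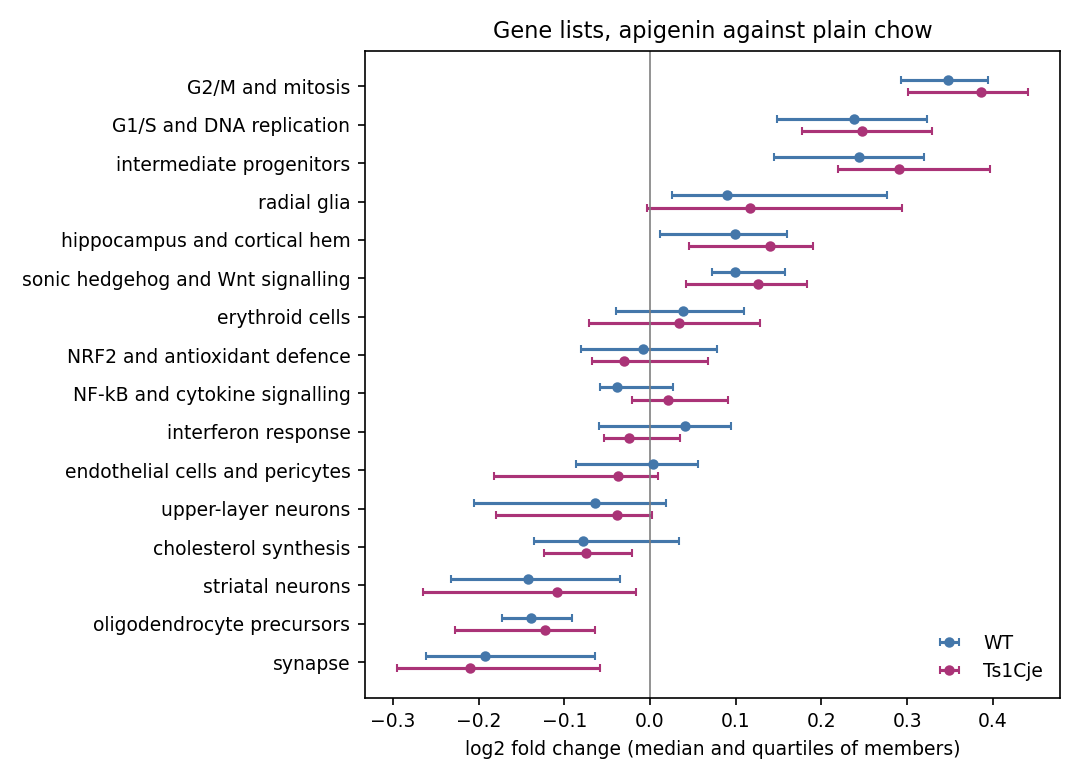
Median log2 fold change of apigenin against plain chow (x axis) over the measured members of the gene lists shown (y axis), with bars from the lower to the upper quartile of members, in WT and in Ts1Cje. The G2/M list lay at 0.35 and 0.39 and the synapse list at -0.19 and -0.21.

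The same lists moved in Ts1Cje embryos. Of the G2/M genes 44 of 48 rose and 0 fell (46 and 0 adjusted over the list alone, median 0.39, adjusted p = 9.5e-32, lost at adjusted p = 0.0692 with an estimated correlation). Among the G1/S genes 33 of 43 rose and 0 fell (37 and 0 adjusted over the list alone, median 0.25, adjusted p = 4.4e-21, held at 0.0307 with an estimated correlation). The kinetochore gene Spc24 rose by 0.40 ± 0.05, Cenpa by 0.46 ± 0.05, Ect2 by 0.57 ± 0.06, Kif11 by 0.47 ± 0.06, Mcm2 by 0.40 ± 0.04, Mcm3 by 0.54 ± 0.06, Rrm2 by 0.53 ± 0.07 and Ccnd2 by 0.39 ± 0.05. Of the intermediate progenitor genes 17 of 21 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.29, adjusted p = 5.1e-14, held at 0.0307 with an estimated correlation), with Gadd45g at 0.63 ± 0.05, Neurog2 at 0.61 ± 0.08 and Btg2 at 0.47 ± 0.07. Of the radial glia genes 14 of 32 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.12, adjusted p = 1.2e-05, lost at 0.148 with an estimated correlation), with Sox2 at 0.40 ± 0.05, Id4 at 0.43 ± 0.06 and Nes at 0.68 ± 0.09, and the faller again Tnc at -0.44 ± 0.06. Of the hedgehog and Wnt genes 10 of 28 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.13, adjusted p = 1.1e-04, lost at 0.0692 with an estimated correlation), with Cdon at 0.40 ± 0.06, Ccnd1 at 0.31 ± 0.07 and Boc at 0.23 ± 0.05. Of the hem genes 6 of 16 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.0205, lost at 0.148 with an estimated correlation), with Wnt8b at 0.52 ± 0.08 and Rspo3 at 0.32 ± 0.06.

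Among the lists that fell in Ts1Cje, the synapse list had 27 of 45 lower and 0 higher (30 and 0 adjusted over the list alone, median -0.21, adjusted p = 1.2e-18, and adjusted p = 0.0084 with an estimated correlation). Gabra5 was at -0.60 ± 0.06, Nrxn2 at -0.43 ± 0.05, Shank1 at -0.51 ± 0.06 and the NMDA receptor subunit Grin2b at -0.33 ± 0.04. The striatal list had 7 of 18 lower and 1 higher (8 and 1 adjusted over the list alone, median -0.11, adjusted p = 3.9e-04, and 0.0307 with an estimated correlation), with Penk at -0.60 ± 0.07 and Drd2 at -0.44 ± 0.06. Oligodendrocyte precursors had 4 of 13 lower and 0 higher (7 and 0 adjusted over the list alone, median -0.12, adjusted p = 4.0e-04, lost at 0.0759 with an estimated correlation). Cholesterol synthesis had 3 of 19 lower and 1 higher (7 and 1 adjusted over the list alone, median -0.08, adjusted p = 0.0279, lost at 0.707 with an estimated correlation). Of 19 upper-layer neuron genes 5 fell and 2 rose (7 and 3 adjusted over the list alone, median -0.04, adjusted p = 0.0221, lost at 0.246 with an estimated correlation), among them Rasgrf2 (-0.51 ± 0.07), Mef2c (-0.33 ± 0.06) and Plxnd1 (-0.27 ± 0.05). Among 30 endothelial and pericyte genes 5 fell and 0 rose (6 and 0 adjusted over the list alone, median -0.04, adjusted p = 0.0205, lost at 0.562 with an estimated correlation), among them Slco1c1 (-0.37 ± 0.06), the VEGF receptor Flt1 (-0.27 ± 0.05) and Eng (-0.24 ± 0.06). In WT the upper-layer list had 6 lower and 2 higher (the same counts adjusted over the list alone, median -0.06, adjusted p = 0.0565). The endothelial list there had 1 lower over all genes and 0 adjusted over the list alone (median 0.0039, mean -0.02, adjusted p = 0.996).

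In Ts1Cje 3291 genes differed between chows, 1638 higher and 1653 lower (limma, adjusted p under 0.05), with a median size of 0.21. Hbb-y was 7.02-fold higher (2.81 ± 0.24), and Hba-x, an embryonic alpha-type globin chosen after its values were seen, was higher by 0.80 ± 0.10, against 0.70 ± 0.10 in WT. Grb10, an imprinted growth factor adaptor, rose by 0.46 ± 0.05, Golm1 by 0.44 ± 0.05, Nde1, a centrosomal protein of cortical progenitors, by 0.45 ± 0.05, and Hnrnpm by 0.35 ± 0.04. Lower were the diacylglycerol kinase Dgkk at -0.75 ± 0.06, Adcy1 at -0.62 ± 0.06, the GABA-B receptor subunit Gabbr2 at -0.62 ± 0.06, the NMDA receptor subunit Grin2d at -0.59 ± 0.06, Rasgef1a at -0.65 ± 0.06, Kndc1 at -0.54 ± 0.05, Neto1 at -0.58 ± 0.06, Gabrg3 at -0.49 ± 0.04, Bend6 at -0.55 ± 0.06 and 1700086L19Rik at -0.52 ± 0.05. Between the 2 genotypes 1021 genes were higher on apigenin in both, 997 lower in both and 1, Trarg1, opposite, where independent lists would share 106 higher and 96.7 lower. The genotypes share no arrays here, and the fold changes correlated at r = 0.73 across genes, above the range of -0.56 to 0.52 of simulated groups with no effect. The simulation and the independent lists treat embryos as independent. Each run of embryo numbers held both genotypes but never both chows. A difference between the chows in litters or sampling would enter both genotypes, so the sharing does not set it apart from apigenin. The count in Ts1Cje was 1332 with the methods' t-test at its unadjusted p threshold, 1895 at the study's threshold and 35 with the G2/M level as a covariate. Averaged over genotypes 5238 genes differed between chows, 2802 higher and 2436 lower. That count was 3178 at the study's threshold.

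**Figure D4:**
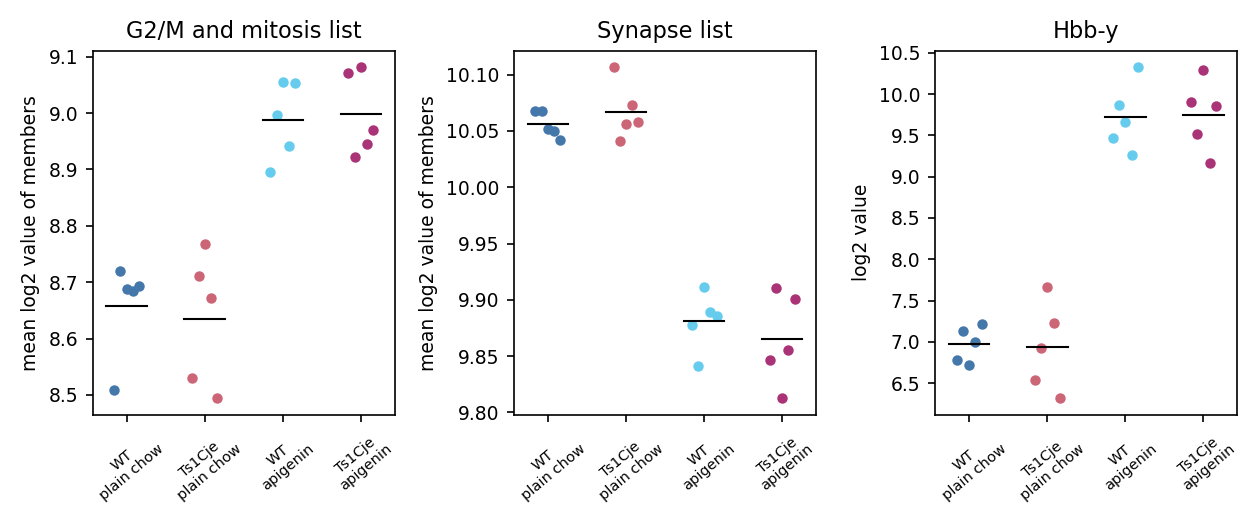
Mean log2 value of the G2/M list, mean log2 value of the synapse list and log2 value of Hbb-y for each embryo (y axes) by genotype and chow (x axis), with each dot an embryo and the line the group mean (n = 5). The G2/M level averaged 8.66 and 8.63 on plain chow against 8.99 and 9.00 on apigenin, and the synapse level 10.06 and 10.07 against 9.88 and 9.87.

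The lists fixed for the known targets of flavones did not shift with apigenin. Of 43 measured NRF2 and antioxidant genes 1 rose and 2 fell in WT (0 and 1 adjusted over the list alone, median -0.01, adjusted p = 0.72) and 2 rose and 5 fell in Ts1Cje (2 and 8, median -0.03, adjusted p = 0.498). Of 9 targets of the aryl hydrocarbon receptor 0 rose and 1 fell in each genotype, also adjusted over the list alone (adjusted p = 0.675 and 0.976), and in Ts1Cje the median (0.0091) and mean (-0.0091) differed in sign. Of 39 NF-kB and cytokine genes 0 changed in WT and 1 rose in Ts1Cje (0 adjusted over the list alone in both, adjusted p = 0.681 and 0.498), and of 44 interferon response genes 1 rose and 1 fell in WT and 0 rose and 2 fell in Ts1Cje (1 and 1, then 0 and 0, adjusted over the list alone, adjusted p = 0.583 and 0.528). The 24 erythroid genes, a marker of blood left in the tissue, had medians of 0.04 and 0.03 (adjusted p = 0.183 and 0.372), with 2 higher and 1 lower in WT and 3 higher and 1 lower in Ts1Cje, the same adjusted over the list alone. The 10 neurotrophin signalling genes had 1 higher and 4 lower in both genotypes (2 and 4 adjusted over the list alone, adjusted p = 0.494 and 0.391).

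The remaining lists did not pass camera in either genotype. Their medians in WT and Ts1Cje were -0.04 and -0.03 for oxidative phosphorylation (adjusted p = 0.125 and 0.0627), -0.05 and -0.06 for glycolysis and hypoxia (0.681 and 0.185), 0.04 and 0.05 for heat shock (0.128 and 0.185), 0.05 and 0.0022 for ribosomal proteins (0.0877 and 0.498) and -0.01 and -0.07 for meninges (0.736 and 0.182). Ganglionic eminence and interneuron genes had 0.05 and 0.07 (0.321 and 0.754), deep-layer and subplate neurons -0.03 and -0.04 (0.494 and 0.441), and distal chromosome 12 had 0.05 and 0.0048 (0.681 and 0.758). Median and mean differed in sign in at least 1 genotype for p53 targets (adjusted p = 0.583 and 0.621), stress of the endoplasmic reticulum (0.15 and 0.754), immediate early genes (0.996 and 0.923), Cajal-Retzius cells (0.583 and 0.391), choroid plexus (0.97 and 0.976), microglia (0.72 and 0.907), diencephalon (0.583 and 0.976), the genes before the segment on chromosome 16 (0.734 and 0.976) and the trisomic segment (0.996 and 0.976). In the segment 8 genes rose and 8 fell in WT (10 and 8 adjusted over the list alone) and 6 rose and 8 fell in Ts1Cje (the same adjusted over the list alone).

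Whether apigenin acted differently in the 2 genotypes was tested as the interaction. With limma 0 genes passed, with 533 at an unadjusted p under 0.05 and a smallest adjusted p of 0.143. The plain 2-factor model without moderation called 1 gene, Olfr61. The genes with the smallest p, none of which passed in limma, were Olfr61 (-0.32 ± 0.05), Trarg1 (0.33 ± 0.07), Pidd1 (-0.28 ± 0.06), Gngt2 (0.34 ± 0.08) and Cfap70 (0.32 ± 0.07). Of simulated changes in the difference, 0% were called at a log2 size of 0.14, 36% at 0.32, 84% at 0.58 and 100% at 1. The simulation held 119 calls in all, which loosens the adjusted threshold, while the data held 0. The shares therefore overstate what could be found in these data. Small differences could be missed. By camera 1 list passed, endothelial cells and pericytes, with a median of -0.07 (adjusted p = 1.0e-04, lost at 0.998 with an estimated correlation), 0 of 30 members singly, over all genes or adjusted over the list alone, and with Flt1 at -0.17 ± 0.07 and Slco1c1 at -0.19 ± 0.08. Between 1 and 6 lists passed when single arrays were left out.

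Whether the treated trisomic embryos moved back toward WT was looked at in the 21 plain chow calls outside the segment. On apigenin 19 of them kept their sign and 8 were called again, and 0 passed the interaction after adjustment. These 8 included Dnah11, Itgb8, Sp4, Tmem196 and Sp8 of distal chromosome 12, Sod1 next to the segment, and Rfx5. The repeated calls therefore say little about genes elsewhere in the genome. While 16 of the 21 plain chow calls were smaller in size on apigenin, 18 of the 21 apigenin calls were likewise smaller on plain chow. Selection by p-value alone can produce this. Among the 63 plain chow calls, 5 were also higher and 1 also lower with apigenin in Ts1Cje, where independent lists would share 4.29 and 0.817. In the opposite direction 12 moved, where independent lists would share 5.14. Of these 12, 6 lay outside the segment, as did the 1 gene lower in both, Cpne6 (-0.33 by genotype and -0.36 with apigenin). These 2 comparisons share the Ts1Cje plain chow arrays, and across genes their fold changes correlated at -0.26, where simulated groups with no effect averaged -0.49. The covariance was -0.0031 against a simulated -0.0034, a difference of 0.00035. With the shared arrays split, so that each comparison had its own, r averaged 0.0056 (-0.12 to 0.16 over the splits). Over 20 such splits, opposite calls averaged 5.25 (4 to 7) against 2.46 for independent lists, and calls in the same direction 2.25 (0 to 6) against 2.28. The splits reuse the same embryos, so no p-value was attached to them. Across all genes, a general move of the trisomic embryos back toward WT was not detectable here.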

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

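The tests of blood, of the dissected regions, of age without Hba-x and of distal chromosome 12 below were chosen only after the results they bear on were seen. The lists of genes that change with age were likewise drawn up after the treatment results had been seen. In groups of 5 embryos a value was singled out where its gap to the nearest other was an unusually large share of the group's range. Chance gives about 1 in 20 such groups, and 35 of 692 pairs of group and value were found (5.06%), against 34.6 by chance.

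The pattern a biologist would most want to follow is that the apigenin embryos had higher levels of cell cycle and progenitor genes and lower levels of synapse genes, in both genotypes. More blood in the samples as the whole cause was argued against, since the erythroid list without the embryonic globins had a largest median of 0.035 and its 9 brighter members medians of 0.11 in WT and 0.0042 in Ts1Cje, the first of these above the bound of 0.1 used for the whole list, but with 2 standard errors added at most 0.707 of the G2/M medians of 0.35 and 0.39. After renewed quantile normalization 0.948 of the G2/M median was left. RMA had already made the arrays alike, so this could change little and does not decide whether array scale before RMA played a part. The largest region median was 0.411 of the G2/M median, and at most 0.713 with 2 standard errors added. These lists were not made to part dividing from maturing layers within a region. The striatal list fell (-0.14 in WT, -0.11 in Ts1Cje) and the hippocampus and hem list rose (0.10 and 0.14), while the other region lists did not pass camera. A different share of tissue in the dissection is therefore left open. A younger stage of the apigenin embryos is also left open, as a hypothesis. Genes listed as rising with age had medians of -0.25 in WT and -0.34 in Ts1Cje, with 8 and 7 of 10 lower. Genes listed as falling with age had 0.16 and 0.19, with 3 of 7 higher, which met the bound of above 0.1. That bound was set before these medians were known, but after the treatment results were seen. Genes of maturing neurons are close in kind to synapse genes, so these lists are not separate evidence of age. In the later test without Hba-x the falling genes had 0.0999 and 0.19, with 2 of 6 higher, the first just below that bound. Lin28a (-0.12 in WT) and Trim71 (-0.02), both listed as falling with age, did not rise. Both lay below the array medians, at mean levels of 7.18 and 7.25, and fold changes of dim genes are understated. An effect of apigenin on development and sampling at another time cannot be told apart from a younger stage. The reason is that no run of embryo numbers holds both chows. Runs within a chow differed by at most 0.072 of the difference between chows. That value lies below the bound set beforehand for setting sampling time aside, but cannot decide it here.

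The next pattern is distal chromosome 12 in Ts1Cje, where Dnah11 was far higher and Sp4, Sp8, Itgb8 and Tmem196 were lower. Spread of the array signal was argued against, since the 4 listed genes that passed in a fit of the plain chow embryos, and the same 4 with Sp8 in a fit of the apigenin embryos, lay apart without overlap and in the same direction in the embryos of the other chow, where chance gives 0.794% without overlap for each. These 9 comparisons covered 5 genes in the same 20 embryos and are not separate results. All 5 had already passed on both chows when this test was chosen, so the chance share does not measure its strength. A copy number or position change covering neighbouring genes is left open. Averaged over chows, Sp4 (-0.44), Sp8 (-0.34), Itgb8 (-0.70) and Tmem196 (-0.50) beyond Dnah11 were lower. The others measured there, Abcb5 and Macc1, were dim. Cdca7l (0.08) and Rapgef5 (0.05) before Dnah11 did not pass. Thus 0 bright genes among the 7 from Dnah11 to the last lower gene failed to pass, but Dnah11 moved opposite to the rest. Averaged over chows 4 other genes of the chromosome also passed, Sec23a (0.10), 4930447C04Rik (0.37), Npc2 (0.15) and Ppp2r5c (0.11). At the rate of the other chromosomes 2.42 of 673 would. These 4 lie before Vipr2, outside this stretch, and so do not bear on it. Copy number itself was not measured. The translocation of the segment to chromosome 12 is background that the arrays cannot test, and strain variants near the breakpoint were not tested.

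In WT on plain chow, replicate 1 lay apart from the other 4 in the level of the G1/S list (a gap of 0.851 of the range), of the G2/M list (0.836) and of the intermediate progenitor list (0.842). Replicate 2 lay apart in Cryzl1 (0.852) and Nrxn2 (0.90), and replicate 5 in Dyrk1a (0.729), Lmo4 (0.790) and Tmem196 (0.727). In Ts1Cje on plain chow, replicate 1 lay apart in Neto1 (0.754) and Smim20 (0.822), replicate 2 in Catsperg1 (0.816), Rspo1 (0.764) and Stard4 (0.823), and replicate 3 in Dgkk (0.722) and Drd2 (0.713). Replicate 4 of that group lay apart in Cbr1 (0.740), and replicate 5 in Tnfrsf1a (0.789) and the level of the hippocampus and hem list (0.853).

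In WT on apigenin, replicate 1 lay apart in Samd9l (0.778) and the level of the distal chromosome 12 list (0.807), replicate 2 in Scd1 (0.724), replicate 3 in Traf2 (0.75) and replicate 4 in Gm7168 (0.713). Replicate 5 there lay apart in Cyp51 (0.723), Gbp2 (0.831), Rgs5 (0.835) and the level of the p53 list (0.748). In Ts1Cje on apigenin, replicate 2 lay apart in Synj1 (0.728) and the level of the endoplasmic reticulum stress list (0.742), replicate 3 in Ache (0.733) and the level of the trisomic segment (0.724), replicate 4 in Rfx5 (0.791), and replicate 5 in Fdft1 (0.887), Impg2 (0.722) and Insig1 (0.867).

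The treatment effect on the endothelial and pericyte list differed between the genotypes by camera (adjusted p = 1.0e-04, median -0.07), with 0 of 30 members past the threshold singly and an adjusted p = 0.998 with an estimated correlation. The list's mean level was 8.60 in Ts1Cje on plain chow. It was 8.54 in WT on plain chow, 8.53 in WT on apigenin and 8.52 in Ts1Cje on apigenin. The list's shifts by genotype on plain chow, with apigenin in Ts1Cje and in the interaction all draw on the Ts1Cje plain chow arrays. They are not separate results. Among the 986 unnamed probe sets, which the comparisons of named genes left out, 2 differed by genotype on plain chow, 1 on apigenin, 105 by chow in WT (10.6%, against 12.2% of the named ones) and 133 in Ts1Cje (13.5% against 16.2%).

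In 100 splits of the arrays, the real one included, both genotype counts of 63 genes stood against at most 2 in any other split. The averaged genotype count of 126 also stood against at most 2. This argues against chance for the counts as a whole. Of each 63 genes, 42 lay in the trisomic segment, which alone would set the real split apart. The 21 genes outside it on each chow, and the 79 averaged, were not counted apart, so the splits do not decide about them. The treatment counts of 2492 genes in WT and 3291 in Ts1Cje stood against at most 7 and 2 in other splits. The averaged treatment count of 5238 stood against at most 1. In each of these, 1 split, the real one, reached the count. For treatment the splits cannot exclude chance differences between litters, because they exchanged single embryos while the chow was given to breeding pairs. For the interaction the count was 0, which all 100 splits reach by construction (with up to 50 genes in another), so this comparison decides nothing there.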

How the results depend on the processing

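The plain 2-factor model and the G2/M level as a covariate were chosen only after the results were seen. No paired analysis was run, because the labels hold no replicate number or litter that links arrays of different groups. The replicate numbers 1 to 5 of each group were given here in deposit order, only to name the arrays. Runs of embryo numbers hold both genotypes and served as blocks, not as pairs. The probe set with the highest mean per gene was not run, since no symbol had more than 1. Dim genes, close to the background of the array, limit what can be detected. Where a value moved, the cause was not tested, unless stated.

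With the methods' t-test after Benjamini-Hochberg adjustment, the genotype count on plain chow was 34 (7 outside the segment) and the treatment count in WT 1641 (1634 outside). At the study's unadjusted p threshold it gave 38 outside the segment for genotype on plain chow, 98 (56 outside) on apigenin, 865 (863) for treatment in WT and 1332 (1323) in Ts1Cje. The plain 2-factor model gave 1 interaction gene, 1 of them outside the segment. At the study's threshold of p and false discovery rate the counts were 1436 (1432) in WT, 1895 (1887) in Ts1Cje, 205 (156) for averaged genotype and 3178 (3163) for averaged treatment. With only the groups compared they were 10 outside the segment for genotype on plain chow and 1574 (1568) for treatment in WT, with fewer arrays to estimate the spread. Without the dimmest 40% of genes the averaged genotype count was 200 (154), and with a trended robust prior 123 outside the segment. The share of higher calls moved from 84.1% to 71.4% for genotype on apigenin at the unadjusted p threshold, and from 78.6% to 67.5% for averaged genotype without the dimmest 40% of genes (from 99 higher and 27 lower to 135 and 65). On plain chow it moved the other way, from 84.1% to 94.1%, with the t-test after Benjamini-Hochberg adjustment. Outside the segment on plain chow, 11 higher and 10 lower became 5 and 2 with that test, 4 and 6 with only the groups compared, and 18 and 10 without the dimmest 40%.

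With the G2/M level as a covariate the treatment counts were 1 (1 outside) in WT, 35 (35) in Ts1Cje and 11 (11) averaged. The covariate differs between the chows and so takes up the difference by construction. Only under it did named genes turn direction: for treatment in WT Rspo3 (-0.011), in Ts1Cje Gli2 (-0.019) and Boc (-0.012), and averaged Son (-0.020), Sp8 (-0.036), Gli2 (-0.0067), Rspo3 (-0.0023), Boc (-0.036) and Lhfpl3 (0.023).

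The number of lists past camera was, with an estimated correlation, 1 for genotype on plain chow and 1 averaged, 5 for treatment in WT, 4 in Ts1Cje and 5 averaged, and 0 for the interaction. With fry, which tests a list without comparing it with other genes, it was 2 for genotype on plain chow, 2 on apigenin, 2 averaged, 0 for the interaction and 19 for averaged treatment. Without the dimmest 40% of genes it was 2 for the interaction and 2 for averaged genotype. The correlation of genotype effects was 0.608 without the dimmest 40% (0.562 outside the segment) and 0.225 as Spearman's rho. That of treatment effects was 0.90 (0.90 outside) and 0.648 (0.647 outside).

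Leaving out each array in turn, the counts ranged from 52 to 79 (13 to 38 outside) for genotype on plain chow, 53 to 68 (13 to 26) on apigenin, 1906 to 2508 (1898 to 2497) for treatment in WT, 2539 to 3532 (2529 to 3518) in Ts1Cje, 0 to 0 for the interaction, 101 to 178 (55 to 131) for averaged genotype and 4793 to 5385 (4768 to 5358) for averaged treatment. Outside the segment WT plain chow replicate 2 gave 38 on plain chow and 131 averaged when left out, WT plain chow replicate 5 and Ts1Cje plain chow replicate 3 gave 13 each, and WT apigenin replicate 1 and Ts1Cje apigenin replicate 3 gave 13 each on apigenin. The segment difference ranged from 0.272 to 0.279 on plain chow and 0.278 to 0.285 on apigenin. The correlations ranged from 0.276 to 0.343 (0.239 to 0.309 outside) between genotype effects, 0.681 to 0.734 (0.681 to 0.734) between treatment effects and -0.342 to -0.216 (-0.350 to -0.221) between genotype on plain chow and treatment in Ts1Cje.

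Lists past camera ranged from 4 to 7 for genotype on plain chow, 1 to 6 on apigenin, 8 to 13 for treatment in WT, 11 to 13 in Ts1Cje, 1 to 6 for the interaction, 2 to 6 for averaged genotype and 9 to 12 for averaged treatment. For genotype on apigenin, 6 passed without WT apigenin replicate 4, 5 without Ts1Cje apigenin replicate 2, 3 without WT plain chow replicate 5 or Ts1Cje plain chow replicate 2, and 2 without WT apigenin replicate 1, 2 or 3 or Ts1Cje apigenin replicate 1. For the interaction, 6 passed without Ts1Cje apigenin replicate 2, 4 without WT plain chow replicate 1, Ts1Cje plain chow replicate 2 or WT apigenin replicate 5, 3 without WT apigenin replicate 1 or 2 or Ts1Cje apigenin replicate 4, and 2 without WT plain chow replicate 2 or 5, Ts1Cje plain chow replicate 3 or WT apigenin replicate 3. For averaged genotype, 2 passed without WT plain chow replicate 3, Ts1Cje plain chow replicate 1, 2 or 4, WT apigenin replicate 1, or Ts1Cje apigenin replicate 3 or 4. Of the named genes' values without single arrays, 6909 kept direction and side of the threshold and 191 kept direction only, and under the other alternatives 4231 and 425 did, 1 passed that had not, and 9 turned. Of the lists' values, 841 and 39 did without single arrays, and 138 and 48 under the others.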

Other observations

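The test of developmental age below was chosen after the treatment results were seen and before its own result was known.

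Genes that are low early and rise in maturing neurons and glia were lower on apigenin, in a list drawn up after the treatment results had been seen. The synaptic calmodulin-binding protein Nrgn was at -0.50 ± 0.09 in WT and -0.54 ± 0.09 in Ts1Cje (n = 5 per group), the neuronal surface protein Thy1 at -0.49 and -0.37, the water channel Aqp4 at -0.51 and -0.50, the sodium pump subunit Atp1b1 at -0.42 and -0.47, and the neurofilament Nefl at -0.27 and -0.35, all past the threshold in limma. Gfap (-0.10 and -0.13) and Nefm (0.05 and -0.04) did not pass. Of the genes listed as falling with age, the chromatin protein Hmga2 (0.26 and 0.33) and the RNA-binding protein Igf2bp3 (0.36 and 0.37) were higher, and Hbb-bh1, another embryonic globin, had 0.04 and 0.19 and did not pass.

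As a hypothesis, Hbb-y and the balance of cell cycle and synapse genes may share an axis of developmental age among embryos of one chow. Over the 10 plain chow embryos the level of Hbb-y correlated with the G2/M level minus the synapse level at r = 0.790 (permutation p = 0.0044, adjusted 0.0087 over 2 correlations; rho = 0.661, p = 0.0450), and over the 10 apigenin embryos at r = 0.738 (permutation p = 0.0159, adjusted 0.0159; rho = 0.770, p = 0.0127, adjusted 0.0254). Without the 2 embryos farthest from the median Hbb-y level r was 0.667 and 0.842, and without any single embryo it stayed at 0.716 to 0.853 and 0.631 to 0.792. Within the runs of 6 embryos r was 0.730 on plain chow (exact p = 0.0889) and 0.848 on apigenin (exact p = 0.0444), and the runs of 4 were too few. Litter, which the labels leave out, stays open as a source of such an axis and was not tested.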
